A study of Daphnia pulex with 4 samples.

How the data were processed

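Whole bodies of adult female Daphnia pulex were compared after 16 days on a control diet or on one holding 50% Microcystis, on 4 two-colour NimbleGen arrays with dye swaps, 2 in each orientation. Per the labels' protocols, total RNA was amplified, made into double-stranded cDNA and labelled with Cy3 or Cy5 random primers. Per the file headers, NimbleScan 2.4.27 extracted one intensity per probe and channel from each scan, with no background column. The arrays lay on 3 slides, with arrays 3 and 4 on one. The authors' value table holds log2 ratios, with the base inferred from the values and the method not given in the sources used here. Its columns have medians of -0.0018, -0.0048, -0.011 and 0.017. They correlated at 0.49, 0.53, 0.50 and 0.53 with the log ratio of Microcystis over control of the probe with the same ID. The positive sign goes with Microcystis over control in all 4 columns, as far as the IDs can be trusted. Of its 134558 rows, 132506 matched 1 probe by ID. In stretches of 2000 rows the correlation of array 1 with the log ratio of the same probe lay between -0.0046 and 0.87, and was under 0.2 in 8 of 68 stretches. The IDs were therefore not taken to go with the values throughout, and no feature, gene model or region was taken from that table.

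From the intensities, background was corrected with normexp (offset 50), log ratios were normalized within arrays by loess with the random control probes at weight 0, and the probes of one feature were averaged. limma 3.58.1 (R 4.3.3) fitted the log2 ratios of Microcystis over control on 4 arrays, two-sided, with Benjamini-Hochberg adjustment over 119311 features and a threshold of 0.05. The random control probes were left out of the test. Passed through the same fit, 2 of 2532 random probes were called. A feature counted as above the random probes on an array and diet if any of its probes exceeded the 95th percentile of that channel's random probes. Gene models are the EXON features that share the leading number of their ID, averaged. They, the runs of adjacent models, the distances to the nearest model and the test of unequal exon features (limma diffSplice) were added after the data were seen. Runs were tested by shuffling calls 1000 times within scaffolds, and among models of like level in 10 classes.

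The design, the tests of features and gene lists, the rule for named features and most alternatives were fixed before the data were examined. The rule named, in the absence of gene names, the 2 features that rose most and the 2 that fell most among those past the threshold, with the same sign on 4 arrays and a mean level above the random probes. Of the 119311 feature IDs and 29544 gene model numbers, 0 matched the 22355 genes of the reference table (assembly ASM2113471v1). The 32 gene lists fixed beforehand were therefore not tested. The slide as a random block was not run, because limma estimates no correlation from 4 arrays on 3 slides. Averaging both arrays of the shared slide, which leaves 3 replicates, and array weights were added in its place and after seeing the data.

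The tests were tested on simulated data. Noise was drawn independently for each feature and array, whereas real features of one gene model moved together and arrays may share an exposure. The false calls therefore do not show how many arise under such dependence. For features, 2%, 78%, 98% and 100% of planted changes of 1, 2, 3 and 4 on the log2 scale were recovered. There were 50 of each, with 6 false calls among 119311 features. With 11931 planted changes of 2, 98.5% were recovered and 4.2% of the calls were false. Recovery thus depended on how many features changed, so these values are not those of the reported lists. For gene models, 40% of changes of 1 and 94% of changes of 2 were recovered, 100 of each, with 8 false calls among 29544. A run with more changed gene models was not made. For unequal exon features, 100% of 200 planted changes of 3 were recovered where features varied separately and 97.5% where they shared a variance.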

Results

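Transcript abundance was compared in whole adult female Daphnia pulex, a freshwater crustacean that filters algae from the water, after 16 days on a control diet of green algae or on a diet in which 50% was Microcystis aeruginosa, a toxic cyanobacterium. Each of the 4 arrays carried RNA of both diets, labelled with a different dye. The Microcystis RNA was in Cy5 on arrays 1 and 4 and in Cy3 on arrays 2 and 3. The arrays measured 119311 features, of which 64895 belonged to the class the files call EXON, 32265 to the class NEIGHBOR and 22151 to the class TAR_ONLY. The EXON features fell into 29544 gene models, read here from the leading number of the feature ID. Between 59.9% and 66.0% of features per array and diet were above the random control probes. The number of arrays, 4, limits the precision of every value. The sources give 3 exposures for 4 arrays and do not say which arrays share one. The limma p-values therefore measure the spread between arrays, part of which may be technical. With fewer exposures than arrays, these p-values may be too small and the counts of calls too large. Averaging the arrays of the shared slide does not settle this, because the slide need not follow the exposure. Shuffles of calls or log ratios among gene models keep the 4 arrays fixed, so their p-values do not measure the spread between arrays.

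The first comparison asked which transcripts differed between the diets. Of the 29544 gene models, 1488 rose and 1693 fell on the Microcystis diet. Among these, 515 rose and 605 fell by more than 2-fold, and 23 rose and 39 fell by more than 4-fold. The median size of the change was 0.90 on the log2 scale. Loess centred the log ratios of each array near 0 (median -0.00069 over all features in the mean of 4 arrays). The near-even split of rises and falls is therefore largely set by the normalization, and a general rise or fall could not be seen. At the level of single features, 2384 rose and 2451 fell of 119311 tested, so that 49.3% of the changed features rose. This share was 40.5% with a normexp offset of 16, 34.5% of 933 calls without array 3 and 71.4% of 7 calls without array 4. The EXON class held 1408 features that rose and 1637 that fell, the NEIGHBOR class 561 and 555, and the TAR_ONLY class 415 and 259, a balance that changed with the background offset and with the arrays used. All counts are from limma with Benjamini-Hochberg adjusted p under 0.05. The feature count of 4835 depended on the processing: it was 205 with a smaller normexp offset of 16, 13362 without background correction, 0 without array 2, 7 without array 4, and 0 when both arrays of the shared slide were averaged. The gene model count of 3181 was 559 without array 2, 235 without array 4, 947 without array 1 and 1570 with the slide averaged.

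**Figure D1:**
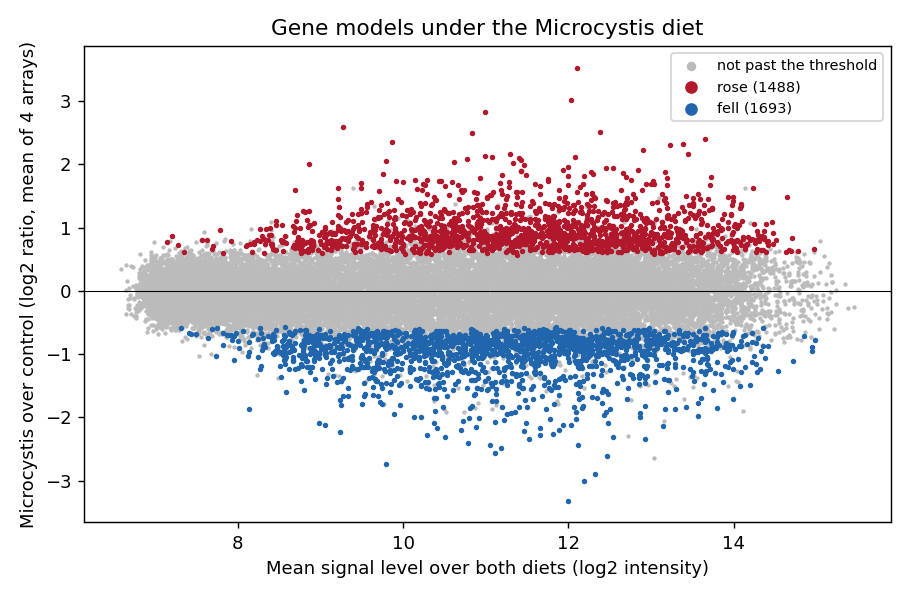
Each point is 1 gene model, with its mean signal level over both diets (log2 intensity) on the horizontal axis and its log2 ratio of Microcystis over control (mean of 4 arrays) on the vertical axis. The 1488 models that rose (red) and the 1693 that fell (blue) lie over most of the range of levels.

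The features that rose most belonged to a single gene model. Both features of gene model 95321 on scaffold 3 rose: exon 1, at 468682 to 468927, by 3.69 ± 0.91 (SD, n = 4) on the log2 scale, which is 12.9-fold, with a limma adjusted p of 0.010, and exon 2, at 469052 to 469431, by 3.37 ± 0.70 (SD, n = 4), which is 10.3-fold, with an adjusted p of 0.010. On the control diet exon 2 was above the random probes on 3 of 4 arrays, which limits the precision of its fold. Exon 1 was measured by 2 probes and exon 2 by 1. The array values of exon 1 lay between 2.59 and 4.82. The feature that fell most was of the TAR_ONLY class, on scaffold 163 at 107953 to 108103. Its log2 ratio was -3.47 ± 1.05 (SD, n = 4), with a limma adjusted p of 0.011. It was measured by 1 probe, with array values of -3.19, -5.01, -2.71 and -2.96. The next was exon 3 of gene model 310509 on scaffold 2, at 3012236 to 3012551, also measured by 1 probe. Its log2 ratio was -3.44 ± 0.79 (SD, n = 4), with a limma adjusted p of 0.010. Exon 4 of that model also fell, with a log2 ratio of -3.32, but was above the random probes on only 2 of 4 arrays on the Microcystis diet. Exon 2 had a log2 ratio of -1.44 with an adjusted p of 0.053, and was above the random probes on 1 Microcystis and 2 control arrays. Their mean with exon 3, -2.73, is therefore imprecise. All 4 named features kept their direction in every setting run, but their calls ended without array 2 (adjusted p = 0.072 for each) and with the slide averaged (0.061 for each), and that of the TAR_ONLY feature without array 4 (0.076), within a range of 0.00071 to 0.076 over the settings. The files do not pair these IDs with gene names, and the genome build behind the scaffold coordinates is not given in the sources used here.

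Exon features of one gene model moved together. In 743 gene models at least 2 EXON features passed the threshold, and in all 743 they went in one direction. Across 21042 gene models with at least 2 features, the log2 ratios of the first and the last feature had a Pearson correlation of 0.65 across models, which are not independent replicates. Unequal change among the exon features of a model was called in 21 of 21042 models, with a median range of 1.94 on the log2 scale between the highest and the lowest feature. None of the 21 had features called in opposite directions. On simulated data with 200 planted changes of 3, more than the 21 models called here, 11.1% of the calls were false where features varied separately. The share was 6.25% where they shared a variance. With nothing planted, 2 and 0 models were called. On the real arrays the test called 0 models when any 1 of the 4 was left out, with 1082 to 1762 models at an unadjusted p under 0.05. All 4 arrays gave 1690 of 21042 models at such a p. Simulated models with nothing planted had 5.9% and 5.1%, so much of these counts can arise by chance.

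The next comparison concerned position in the genome, a question chosen after the data were seen. Gene models next to each other on a scaffold changed in one direction more often than chance placement gave. Among adjacent pairs in which both models changed, 505 went in one direction and 142 in opposite directions. Over all 26716 adjacent pairs, called or not, the log2 ratios of neighbours had a Pearson correlation of 0.20. The count of 505 was 97 without array 1, 48 without array 2 and 22 without array 4. Of changed pairs, the share in one direction was 78.1% with all arrays and 89.8%, 92.3% and 95.7% in these settings. Over all settings run it was 73.3% to 95.7%. Shuffling the calls within scaffolds gave 233 same-direction pairs on average and at most 282 (permutation p = 0.001, the smallest that 1000 shuffles can give). Runs of at least 3 adjacent models changed in one direction numbered 84, of which 33 rose and 51 fell, against at most 37 after shuffling. There were 13 such runs without array 1, 7 without array 2, 4 without array 4, 32 with the slide averaged and 31 with offset 16. Other settings gave more: 135 without background correction, 128 without dim features, 180 with array weights and 190 at an adjusted p under 0.10.

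Of these runs, 7 held at least 5 gene models, and their coordinates were chosen after the values were seen. The longest lay on scaffold 18 at 1165384 to 1193129, where 13 adjacent models fell, with a mean log2 ratio of -0.95 ± 0.14 (SD, n = 4) and all 36 of their exon features below 0. On scaffold 11, 7 models at 485 to 28651 fell, with a mean of -1.22 ± 0.53 (SD, n = 4). On scaffold 78, 5 models at 111898 to 144408 fell, with a mean of -0.99 ± 0.43 (SD, n = 4). The largest mean rise was on scaffold 3, where 6 models at 2387310 to 2398636 rose by 1.85 ± 0.71 (SD, n = 4). Runs of 5 models rose on scaffold 46 at 227654 to 240123, by 1.29 ± 0.28 (SD, n = 4), on scaffold 72 at 210281 to 219959, by 1.23 ± 0.34 (SD, n = 4), and on scaffold 14 at 1098141 to 1112780, by 0.83 ± 0.15 (SD, n = 4). The 4 arrays had the same sign in each of the 7 regions, which choosing them by calls on these arrays favours. The count of 7 was 0 without array 1, array 2 or array 4 and at an adjusted p under 0.01, 4 without array 3, and 2 with the slide averaged or with offset 16. It was 19 without dim features, 23 with array weights and 24 at an adjusted p under 0.10. The mean of each region kept its sign in the settings run on it.

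**Figure D2:**
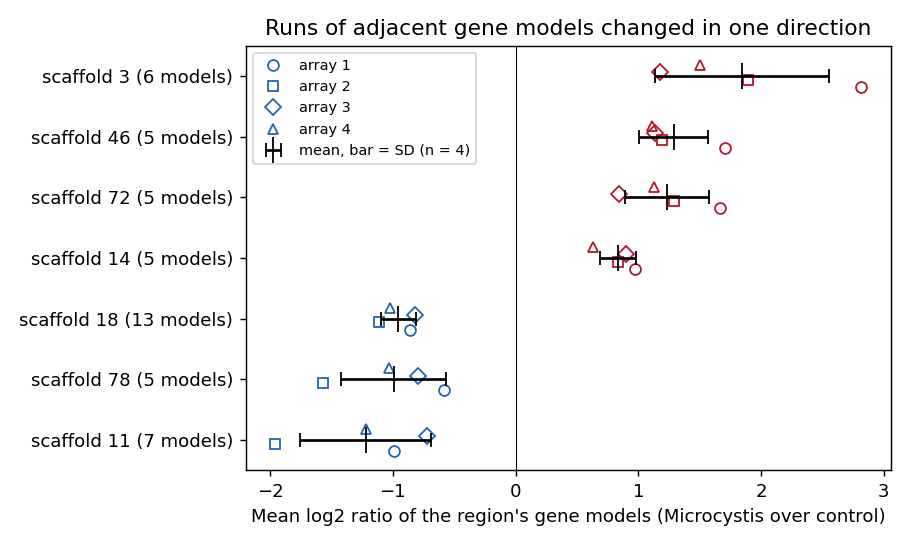
The horizontal axis gives the mean log2 ratio (Microcystis over control) of the gene models in each of 7 runs, with 1 open symbol per array, the mean as a vertical tick and the SD over 4 arrays as a bar. The runs on scaffolds 3, 46, 72 and 14 lie above 0 and those on scaffolds 18, 78 and 11 below it on each array.

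NEIGHBOR features followed the gene model closest to them. Among the 18436 NEIGHBOR features within 200 bases of a gene model or inside it, log2 ratios correlated with those of the model at a Pearson r of 0.56 and a Spearman rho of 0.52, across features, which are not independent replicates. Shuffled models gave an absolute r of at most 0.031 (permutation p = 0.001, the smallest that 1000 shuffles can give). Both the feature and its model passed the threshold in 431 cases, and 429 of these went in one direction. The correlation was 0.26 at 1001 to 2000 bases and 0.022 beyond 10000 bases. TAR_ONLY features had a correlation of 0.55 at 1 to 200 bases and 0.10 beyond 10000 bases.

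**Figure D3:**
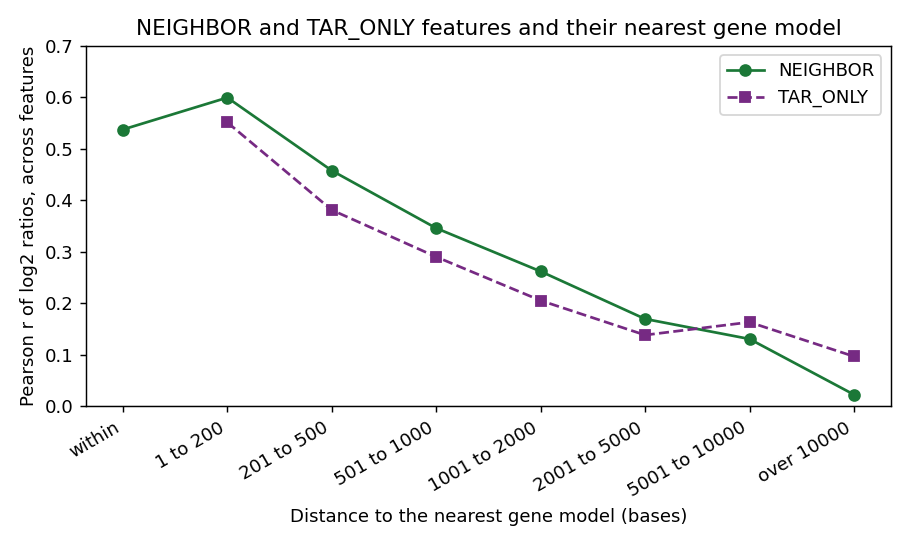
The horizontal axis gives the distance of a feature to its nearest gene model in bases, in classes, and the vertical axis the Pearson correlation, across features, between its log2 ratio and that of the model. Circles (NEIGHBOR) go from 0.60 at 1 to 200 bases to 0.022 beyond 10000 bases, and squares (TAR_ONLY) from 0.55 to 0.10.

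The agreement of the dye swaps with each other was checked on the log ratios themselves. With every array turned to Microcystis over control, the 6 pairs of arrays correlated at 0.18 to 0.47 across features. The 4 pairs of opposite dye orientation were among them, at 0.18 to 0.46. Turning all 4 arrays the other way would leave these correlations unchanged. Which diet is over which therefore rests on the labels and on the channel of each dye. The arrays on the shared slide, 3 and 4, correlated at 0.27. Of all features, 31.4% had the same sign on 4 of 4 arrays, where independent arrays without any diet difference would give 1 feature in 8. Of the 4835 changed features 100% did, which a small p over the same arrays nearly forces.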

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

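The tests of chance placement in this part were chosen after the result was seen. In 1 of 20 reported sets of 4 array values, 1 array stood apart from the other 3. In the region on scaffold 46 array 1 had a mean log2 ratio of 1.71, whereas the others lay between 1.12 and 1.19. Chance flags about 1 in 20 such sets.

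Adjacent gene models changed in one direction in 505 pairs, more than in any of 1000 shuffles within scaffolds (at most 282) or among models of like level (at most 263), which argues against chance placement of the calls. Overlapping or contiguous models of one transcript are argued against as the whole cause, since 69.1% of changed pairs 2000 bases or more apart went in one direction (exact 95% interval 63.2% to 74.6%, taking pairs as independent, which pairs that share a model are not). The share went from 85.4% under 500 bases to 71.4% at 2000 to 5000 bases, was 72.7% of 55 pairs at 5000 to 10000 bases (59.0% to 83.9%), and was 48.3% of 29 pairs beyond 10000 bases (29.4% to 67.5%). Position on the array is argued against by the distance between the probes of such pairs, which was 1.01 times that of random pairs. Cross-hybridisation between neighbouring copies of a gene stays open, because probe sequences were not used here. Joint regulation of neighbours by the diet also stays open, as untested.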

How the results depend on the processing

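Tests of gene models, pairs, NEIGHBOR features and unequal exons, array weights and slide averaging were chosen after the data were seen. Against 4835 changed features as reported, limma called, over all features tested in each setting, 0 with the slide averaged (23155 at an unadjusted p under 0.05), 205 with offset 16, 13362 without background correction, 10840 without dim features, 11161 with a variance trend, 8953 in a separate-channel model, 10616 with array weights, 14155 rows of the authors' values tested singly, 12481 at an adjusted p under 0.10 and 5 under 0.01. Leaving out 1 array gave 0 (22537 at an unadjusted p under 0.05) to 1519. Against 3181 gene models, it called 1570 with the slide averaged, 1738 with offset 16, 4936 with weights, 5351 at 0.10 and 282 at 0.01, and 235 to 2581 with 1 array left out. Against 505 same-direction pairs, the counts were 196 with the slide averaged, 826 without background correction, 204 with offset 16, 1014 with weights, 1119 at 0.10 and 29 at 0.01, and 22 to 413 with 1 array left out. Their share of changed pairs, 78.1% as reported, was 73.3% to 95.7% over the settings. Against 21 unequal models, the counts were 0 with the slide averaged (1493 at an unadjusted p under 0.05), 228 without background correction, 0 with offset 16 (1529 at an unadjusted p under 0.05), 8 with median centring, 10 without dim features, and 0 with any 1 array left out. The NEIGHBOR correlation of 0.56 was 0.69 without dim features, and otherwise 0.52 to 0.56 with 1 array left out. Fewer arrays or features tested and the threshold act in part by construction. Which array was left out also mattered. Without arrays 1, 2, 3 and 4 in turn, 1519, 0, 933 and 7 features and 947, 559, 2581 and 235 gene models were called. The cause of that difference, and of the other settings, was not tested. Each named feature and region kept its direction in the settings run on it, whereas the majority direction of changed features and of TAR_ONLY calls turned in some settings. The dye term called 0 features for dye itself (9075 of 119311 at an unadjusted p under 0.05). In the simulation of the feature test with nothing planted, 5.1% of features had such a p. The slide block and the gene lists were not run. Signal over background limits dim features.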

Other observations

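The comparison of classes on matched levels was chosen after the result was seen. Of the 667 changed TAR_ONLY features on scaffolds that hold a gene model, 192 lay over 5000 bases from the nearest one, and 159 of these rose while 33 fell. Of the 475 nearer ones, 251 rose and 224 fell. Over all TAR_ONLY features on such scaffolds, called or not, the median log2 ratio was 0.15 beyond 5000 bases and -0.010 nearer. In the mean over the arrays the far features were thus shifted upward as a group, so the excess of rises is not particular to the changed ones. The spread of this shift over the arrays is not given here, so a few arrays may carry it. This distance was also chosen after the data were seen, and 26.2% of all 21920 TAR_ONLY features on such scaffolds lay beyond it, against 28.8% of the changed ones. The share that rose beyond it, 82.8%, was 16.7% of 6 calls with offset 16 and 38.5% of 26 without array 3, with no such calls without array 2, without array 4, with the slide averaged or at an adjusted p under 0.01, and 78.7% to 87.4% in the other settings. Of 674 changed TAR_ONLY features, 61.6% rose in the reported setting, against 14.3% of only 14 with offset 16 and 42.5% of 80 without array 3. Within the other settings that called any such feature, the share stayed within 10 percentage points of the reported one.

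NEIGHBOR and TAR_ONLY features lay above EXON features by a median of 0.055 ± 0.092 (SD, n = 4) on the log2 scale, and by 0.067 ± 0.101 (SD, n = 4) when matched on level (exact sign-flip permutation p = 0.50, where 4 arrays allow no less than 0.125). Arrays 2 and 4 carried the difference, at 0.19 and 0.10, while arrays 1 and 3 had -0.026 and -0.0028. With this spread the part of signal level cannot be told apart.

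The 4 arrays allow 8 exchanges of the channels, too few for a share under 0.05. Turning only some arrays also puts any diet difference into the spread between arrays, which lowers the calls of the other exchanges. Their counts are therefore not what chance alone would give. The real arrangement called 4835 features and the highest other 0, with 1 of 8 exchanges as large. For gene models these were 3181 and 6, again 1 of 8, and for unequal exon features 21 and 0, again 1 of 8. The exchange that follows the dyes called 0 features, with 4269 at an unadjusted p under 0.05, and the one that follows the shared slide called 0, with 1250. Of 119311 simulated features with nothing planted, 5.1% had such a p, and both counts lie below that share.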
